A study of Homo sapiens with 12 samples.

How the data were processed

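The series holds 12 libraries of total RNA from the human cell lines MV4-11 and OCI-AML3, 3 for each line under DMSO and 3 under 5 nM AC220, all at 24 h. Per the labels' protocols, RNA was DNase-treated and libraries were made with the Lexogen QuantSeq 3' mRNA kit, which reads the ends of transcripts, so that a gene's count does not grow with its length and isoforms with another 3' end can be missed. The submitters' processing notes name bcl2fastq 2.17.1.14, FastQC 0.11.6, cutadapt 1.9.1, HISAT2 2.0.4, Subread 2.0.0, featureCounts, R 3.6.1, limma 3.42.2 and the genome build hg19. The annotation, the strand setting, the treatment of reads with several positions and the filters were not given in the sources used here. Reads of near-identical genes and of overlapping genes may therefore be divided or lost, and no coordinates are given.

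The authors deposited raw counts per gene symbol, 1 column per library. The count table had 19505 rows, of which 19127 had a symbol found in the gene name table. A row without a symbol held 0.00343% to 0.00503% of a library's counts and was left out of library sizes and tests. In 13 rows the symbol had been turned into a date; they were kept in the tests and are not named. Totals ran from 10877198 to 16918761 counts, so that 3 counts, taken as the floor where a gene had none, amount to 0.177 to 0.276 CPM in a library. The authors also deposited a table of normalised log2 values of 11075 genes, named as a voom-limma output. Those log2 values matched voom with quantile normalization on TMM-scaled counts to within 0.00386, and they were used only as an alternative input. No column of other samples was present.

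Replicates were compared before use. No pair of libraries held identical values, and chi-square per degree of freedom between replicates of a group lay between 2.86 and 11.2, so each library was counted as a replicate. The highest values, 10.0 and 11.2, were those of MV4-11 AC220 replicate 1 against the other libraries of its group.

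Genes were filtered with filterByExpr on the 4 groups, which left 12392, and scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust estimation) on the counts of all 12 libraries with a mean per group, which left 8 residual degrees of freedom, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Contrasts were AC220 against DMSO in each line, the difference of these contrasts, and MV4-11 against OCI-AML3 under DMSO. The common biological coefficient of variation was 8.28%. CPM are scaled by TMM, and are given as mean ± SD of 3 libraries. Ratios with 1 to 3 counts in a group have 95% counting intervals, which cover counting error only, since QuantSeq reads without molecular identifiers are not independent molecules. Fold changes against a group with no counts are bounds at 3 counts over the group.

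Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. The design, 25 gene lists with 435 entries, the alternatives and the rule for named genes were set before the data were examined. LDHA, MCL1, BCL2L1, HOXA9 and HOXA10 stand in 2 lists each. Named genes are 24 key genes of FLT3 signalling, serine synthesis and amino acid stress, of which 1 had no row in the count table and was not analysed here, and the genes with the largest changes: 10 in each direction for AC220 in MV4-11 and 5 in each direction for the other contrasts. The latter needed an adjusted p under 0.05, a mean count of at least 20 in the higher group and no overlap between the libraries of both groups, and could not be pseudogenes, clone names or Y-linked. In each list the members with the smallest adjusted p are named, and members outside the rule where few went against the list. Genes of the lists with no row in the count table were not analysed here.

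The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of the real samples over 12392 genes, with 50 genes changed by each of 4 sizes. In the simulated MV4-11 comparison 76% of 50 genes with a log2 change of 0.5, 94% with 1 and 100% with 2 were recovered, and 7.04% of calls were unchanged genes. In the simulated OCI-AML3 comparison these shares were 70%, 92% and 98%, with 4.76%. Far fewer genes changed in the simulation than the 7228 called in MV4-11, and its genes varied independently within a library. These shares therefore do not cover a change of most genes, nor variation between libraries that many genes share.

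Alternatives were median-ratio size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, limma on the deposited normalised values, a replicate block, fits of the compared libraries alone, thresholds of 0.01 and of an absolute log2 fold change of 1, and leaving out each library. Chosen after seeing the data were counts thinned to the smallest library, a correction for the GC content of the last 500 bases of transcripts in a GRCh38 annotation, a library score as a covariate with 100 random covariates as its control, and leaving out both OCI-AML3 libraries numbered 3. A GC content was found for 99.2% of tested genes.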

Results

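RNA was measured by 3' mRNA sequencing in 2 human acute myeloid leukaemia (AML) cell lines, MV4-11 and OCI-AML3. MV4-11 carries an internal tandem duplication of the receptor tyrosine kinase FLT3, and OCI-AML3 carries a mutated NPM1 and no such duplication. Cells of each line were exposed for 24 h to DMSO, the vehicle, or to 5 nM AC220 (quizartinib), a small-molecule inhibitor of FLT3. Each of the 4 groups held 3 libraries. Total counts per library ran from 15041493 to 16918761 in MV4-11 DMSO, from 11419454 to 13328968 in MV4-11 AC220, from 13013381 to 13455082 in OCI-AML3 DMSO and from 10877198 to 14458640 in OCI-AML3 AC220. The first principal component of log2 CPM (counts scaled to a common library size) held 81.7% of the variance and the second 11.3%. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

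The first comparison asked which transcripts responded to FLT3 inhibition in the FLT3-mutant line, with serine synthesis as the stated interest of the series. In MV4-11, transcripts of serine synthesis, of the amino acid stress response under the transcription factor ATF4, of amino acid transport and of the cell cycle were lower after AC220. PHGDH, the enzyme of the first step of serine synthesis from glycolysis, fell from 323 ± 7.40 to 8.50 ± 0.585 CPM (SD, n = 3 per group), 37.9-fold. PSAT1, the next enzyme of that pathway, fell from 569 ± 27.7 to 30.4 ± 2.78 CPM, 18.6-fold, and PSPH, the last, fell from 71.5 ± 3.12 to 14.6 ± 0.886 CPM, 4.90-fold. Lysosomal genes rose, and of 20 monocyte and granulocyte genes 12 rose and 5 fell. Of 12392 genes tested, 7228 (58.3%) changed, 3899 up and 3329 down, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 1206 rose and 1083 fell by at least 2-fold. Rises and falls are relative to the other transcripts of a library, since CPM do not measure the amount of RNA per cell.

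Among the 14 measured genes of serine synthesis and one-carbon metabolism, 12 fell and 2 rose, with the same numbers when adjusted over the list alone. The log2 fold change was -5.24 (SE 0.0940, adjusted p = 1.42e-26) for PHGDH and -4.22 (SE 0.0765, adjusted p = 1.42e-26) for PSAT1. It was -4.43 for ALDH1L2 and -2.15 for MTHFD2, mitochondrial folate enzymes. SHMT2, which moves the one-carbon unit of serine to folate in mitochondria, fell by 1.28. SHMT1, the cytosolic serine hydroxymethyltransferase, rose by 0.41. The list was lower than other genes by camera (median log2 fold change -2.00, adjusted p = 1.29e-08, and 0.00243 with an estimated correlation).

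All 19 measured genes of the ATF4 and amino acid stress list fell, 19 also when adjusted over the list alone (camera adjusted p = 2.99e-14). Their median log2 fold change was -3.43, or -2.92 with STC2, which had no counts in MV4-11 AC220, at its bound. ATF4 itself fell from 922 ± 33.8 to 272 ± 40.3 CPM. ASNS, asparagine synthetase, fell 13.4-fold (log2 fold change -3.74) and TRIB3, a pseudokinase induced by stress, 46.9-fold (log2 fold change -5.55). GPT2 and PCK2, mitochondrial enzymes of alanine and phosphoenolpyruvate metabolism, fell by 3.72 and 3.43 on the log2 scale. CHAC1, which degrades glutathione, fell by 4.88 and DDIT3, also known as CHOP, by 2.36. Of 13 amino acid transporters, 12 fell and SLC7A6 rose (0.32), with the same numbers adjusted over the list alone. The subunits of the large neutral amino acid transporter, SLC7A5 and SLC3A2, had log2 fold changes of -3.83 (SE 0.0761, adjusted p = 1.19e-25) and -2.67. SLC7A1, which carries cationic amino acids, had -2.44, SLC1A5, which carries glutamine, -2.42, and SLC7A11, the cystine-glutamate exchanger, -3.12. Among 20 cytosolic aminoacyl-tRNA synthetases, 18 fell (19 adjusted over the list alone), led by GARS (-2.86), WARS (-2.43) and MARS (-2.33), and QARS rose (0.62). Camera placed transporters and synthetases below other genes (adjusted p = 1.18e-09 and 3.27e-12).

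**Figure D1:**
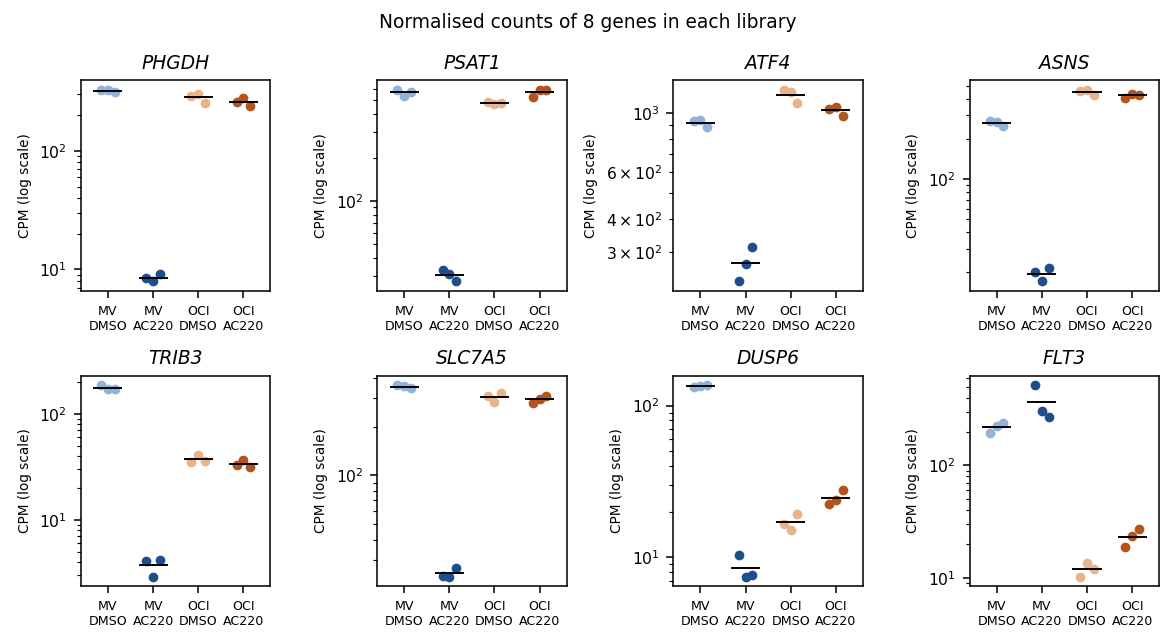
CPM on log axes of 8 genes in each of the 12 libraries, with 1 point per library and a line at the group mean (MV, MV4-11; OCI, OCI-AML3; n = 3 per group). PHGDH stood at 323 CPM in MV4-11 DMSO and 8.50 CPM in MV4-11 AC220, against 284 and 258 CPM in OCI-AML3, and FLT3 at 218 and 364 CPM in MV4-11.

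Output of the MAPK pathway, which lies downstream of FLT3, was lower in MV4-11 after AC220. In this list 12 of 16 measured members fell and none rose (12 adjusted over the list alone, camera adjusted p = 1.23e-05), with a median of -2.37, or -2.41 without SPRY4. DUSP6, a phosphatase of ERK, fell from 135 ± 1.70 to 8.49 ± 1.66 CPM (log2 fold change -3.97, SE 0.117, adjusted p = 8.39e-22). IER3 fell by 4.23, the ETS factor ETV5 by 3.89 and DUSP5 by 4.51 on the log2 scale. SPRY4 had no counts in any MV4-11 library. Among 15 STAT5 targets 8 fell and BCL6 rose, 8 and 1 also when adjusted over the list alone. The camera call on this list (adjusted p = 0.000696) was lost at adjusted p = 0.0565 with an estimated correlation. The members with the smallest p were the D-type cyclins CCND3 (-1.49) and CCND2 (-1.34), the kinase PIM3 (-0.97) and the cytokine OSM (-1.64). PIM1 fell by 1.98 (SE 0.247) and CISH by 0.58 (SE 0.101). PIM2 (-0.17, adjusted p = 0.0586), SOCS2 (-0.02, adjusted p = 0.923) and MYC (-0.91, adjusted p = 0.0645) did not pass the test. PIM2 passed it without OCI-AML3 AC220 replicate 3 (adjusted p = 0.0349), with no filter on low counts (0.0343), by limma-voom (0.0327) and in the 6 MV4-11 libraries alone (0.00670). MYC passed it by DESeq2, limma-voom and limma on the deposited normalised values (adjusted p = 0.0268, 0.00189 and 0.00735), and without MV4-11 AC220 replicate 1 (-1.42, adjusted p = 0.00820), where it stood at 35.9 CPM against 16.6 and 15.7 CPM in the other AC220 libraries. FLT3 rose from 218 ± 22.8 to 364 ± 133 CPM (log2 fold change 0.74, SE 0.236, adjusted p = 0.0248). That call was lost in the fit of the 6 MV4-11 libraries alone (adjusted p = 0.119), with a replicate block (0.0902), without MV4-11 DMSO replicate 1 (0.0813) and without MV4-11 DMSO replicate 2 (0.0591). MV4-11 AC220 replicate 1 stood apart for FLT3, at 516 CPM against 306 and 269 CPM in the other AC220 libraries, and without it the log2 fold change was 0.40.

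Cell cycle genes fell together in MV4-11. All 25 measured DNA replication genes and all 20 mitosis genes fell, also when adjusted over the list alone (camera adjusted p = 4.31e-19 and 3.06e-19). RRM2, a subunit of ribonucleotide reductase, had a log2 fold change of -3.80, MCM4 and MCM3 of the replicative helicase -2.60 and -2.15, MKI67, the proliferation antigen, -2.87, and TOP2A, a topoisomerase, -2.63. Of 24 MYC and nucleolar genes 22 fell (23 adjusted over the list alone, camera adjusted p = 4.34e-09). These included LDHA (-1.67), TCOF1 (-1.36) and NOP56 (-0.99), while WDR74 rose (1.78). In purine and pyrimidine synthesis 13 of 16 fell, with PFAS (-1.48), CTPS1 (-1.18) and GART (-1.14) first by p. In glycolysis 16 of 20 fell, with the glucose transporter SLC2A3 (-3.39) and LDHA (-1.67) first. In cholesterol and fatty acid synthesis 13 of 21 fell, with HMGCS1 (-1.56), SCD (-1.03) and FASN (-1.04) first, and 2 rose, MVD and SREBF2. Numbers for these 3 metabolic lists did not change when adjusted over the list alone, and camera called each lower (adjusted p = 4.55e-07, 3.43e-07 and 0.000235).

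Lysosome and autophagy genes rose in MV4-11, with 14 of 20 up and 2 down, MAP1LC3B and ULK1, both of autophagosome formation (14 and 3 adjusted over the list alone, camera adjusted p = 0.000235). The membrane protein LAMP1 rose by 1.04 on the log2 scale, the protease CTSS by 1.32 and the autophagy gene GABARAPL1 by 2.29. Of 20 monocyte and granulocyte genes 12 rose and 5 fell, also when adjusted over the list alone. Receptors for colony-stimulating factors rose (CSF1R 2.23, CSF3R 1.45), as did the macrophage antigen CD68 (2.45). Among those that fell were the Fc receptor FCGR1A (-1.46), the NADPH oxidase subunits NCF1 and CYBB (-0.74 and -0.94) and the endotoxin co-receptor CD14. Of 16 genes of immature myeloid cells 10 rose and 2 fell, CTSG (-0.60) and GATA2 (-1.77), also when adjusted over the list alone. SOX4 (1.31), AZU1 (1.37) and CEBPA (0.51) rose. The camera calls on these 2 myeloid lists (adjusted p = 0.0385 for each) were lost at adjusted p = 0.0658 with an estimated correlation. Of 15 heat shock and unfolded protein genes 9 fell, XBP1 (-1.47), HSPA8 (-1.06) and HSP90AA1 (-0.73) among them, and 3 rose (10 and 3 adjusted over the list alone). HSPA1A, HSPA1B and HSP90B1 rose, of which the first pair are near-identical copies whose reads the counting could have divided. Its camera call (adjusted p = 0.00255) was lost at adjusted p = 0.167 with an estimated correlation.

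Camera called 16 of 21 lists in MV4-11, 13 lower and 3 higher, and 12 of the 16 calls held with an estimated correlation. Fry, which makes no comparison with other genes, called 17 lists, among them those lost with an estimated correlation. Genes of FOXO targets and growth arrest went both ways, with 8 up and 7 down of 20. The cell cycle inhibitor CDKN1A fell by 2.35 and PIK3IP1, an inhibitor of PI3K, rose by 2.44, and the list's median (0.29) and mean (0.02) were above 0 while camera pointed down (adjusted p = 0.939). In the BCL2 family 4 rose and 6 fell of 15. The pro-apoptotic members BMF and BCL2L11 (BIM) rose by 2.14 and 0.70, and BBC3 (PUMA), BCL2A1 and PMAIP1 (NOXA) fell by 0.91, 1.71 and 0.62 (camera adjusted p = 0.765; the list's median was -0.04 and its mean 0.08). Of 20 interferon response genes 10 fell, USP18 (-2.71), IFIT2 (-3.15) and IFIT1 (-2.89) first, and 3 rose, among them STAT2 (1.27), and the list was not called (camera adjusted p = 0.172). HOXA genes (3 of 7 up, HOXA10 by 0.29) and mitochondrially encoded transcripts (5 of 13 up, 3 down) were not called by camera either (adjusted p = 0.338 and 0.973). Fry did call HOXA genes, as higher (adjusted p = 0.00137). Numbers for these 5 lists did not change when adjusted over the list alone. Lists with fewer than 5 tested members had no camera test, and their genes adjusted over the list alone gave the numbers found over all genes. Of 4 HOXB genes HOXB3 rose (0.65), of 2 erythroid and megakaryocyte markers EPOR fell (-1.34), of 4 lymphoid markers 3 rose, NKG7 (1.08), CD79A (2.91) and PAX5 (2.14), and of 3 epithelial and stromal markers KRT8 rose (0.58).

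**Figure D2:**
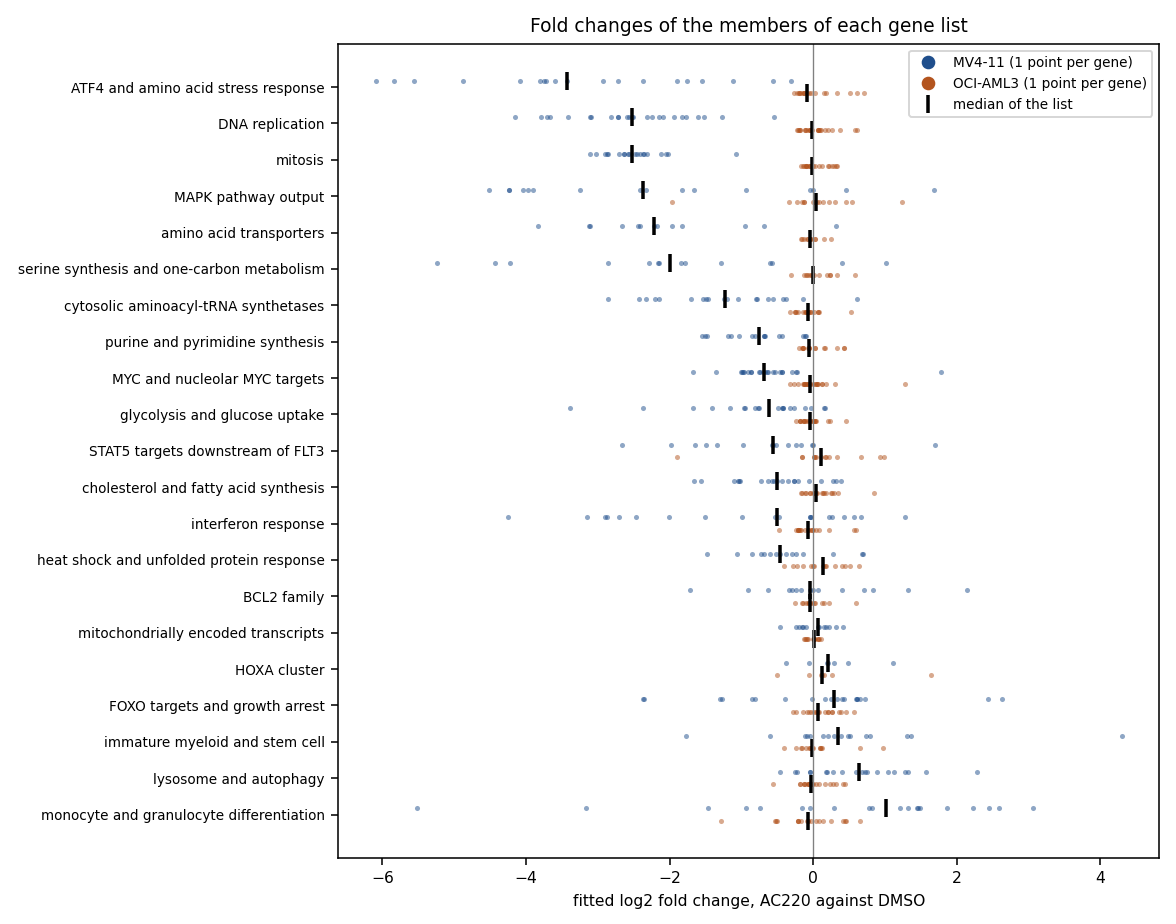
Fitted log2 fold changes, AC220 against DMSO, of the members of the 21 lists with a camera test, 1 point per gene for MV4-11 (blue) and OCI-AML3 (orange), with a bar at each median. The ATF4 list had a median of -3.43 in MV4-11 and -0.09 in OCI-AML3, and DNA replication -2.53 and -0.01.

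Among the largest rises in MV4-11 was that of NLRP4, a gene of the NLR family with no counts under DMSO, at least 33.7-fold higher after AC220 against a floor of 3 counts over the group. IGF1, insulin-like growth factor 1, rose from 1.77 ± 0.338 to 133 ± 23.8 CPM, and LGALS2, galectin 2, from 0.268 ± 0.0668 to 32.6 ± 3.32 CPM. ENHO rose from 0.367 to 16.8 CPM, SLC4A3, an anion exchanger, from 0.0856 to 4.90 CPM, REPS2 from 0.101 to 4.48 CPM and TINAGL1 from 0.0857 to 3.26 CPM. ST8SIA6, TMEM176A and PTGDS had 2 or 3 counts in all under DMSO, which gave ratios of 58.9 (95% counting interval 15.8 to 494), 44.3 (11.8 to 374) and 38.8 (12.8 to 192). Among the largest falls, OCSTAMP, a membrane protein of osteoclast fusion, fell from 62.4 ± 4.01 to 0.117 ± 0.0567 CPM and ADM2, a peptide hormone of the calcitonin family, from 29.4 ± 1.39 to 0.172 ± 0.0914 CPM. No counts were left after AC220 for GDAP1L1 (at least 71.0-fold lower), DCSTAMP (42.3), XIRP1 (39.5), AKR1C2 (35.8), GAGE10 (27.9), KLHDC7B (17.1) and GABRG1 (16.1). EGR3, an immediate early transcription factor, kept 2 counts (ratio 99.2, 27.2 to 824). AKR1C2 and GAGE10 have close paralogs, so the counting could have divided their reads. By the rule that named these 20 genes, the 3 libraries of one group lay outside the range of the other, which chance gives for 10% of unchanged genes.

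The second comparison put the same exposure in OCI-AML3, where fewer genes changed. FLT3 itself stood at 11.9 ± 1.63 CPM under DMSO and 23.1 ± 4.23 CPM under AC220 (log2 fold change 0.97, SE 0.324, adjusted p = 0.135). It passed the test without MV4-11 AC220 replicate 1 (0.97, adjusted p under 0.05), by DESeq2 (adjusted p = 0.0119), by limma on the deposited normalised values (0.0486) and in the 6 OCI-AML3 libraries alone (0.00147). MTHFD2 (0.24, adjusted p = 0.0526) passed with no filter on low counts (0.0131), by limma-voom (0.0441), with a replicate block (0.0309), in the 6 OCI-AML3 libraries alone (0.0339), and without MV4-11 AC220 replicates 1 (0.0130) or 3 (0.0367), OCI-AML3 DMSO replicate 3 (0.0200) or OCI-AML3 AC220 replicate 1 (0.0162). PHGDH stood at 284 ± 26.7 CPM under DMSO and 258 ± 19.0 CPM under AC220 (log2 fold change -0.13, SE 0.0692, adjusted p = 0.272). ATF4 (-0.20), ASNS (-0.09), TRIB3 (-0.16) and SLC7A5 (-0.04) did not pass the test either. PSAT1 rose by 0.24 (SE 0.0635, adjusted p = 0.0304), DUSP6 by 0.54 (SE 0.112, adjusted p = 0.0105) and BCL2L11 by 0.59 (SE 0.135, adjusted p = 0.0180), and PSPH fell by 0.31 (SE 0.0816, adjusted p = 0.0281). Without OCI-AML3 DMSO replicate 1, DMSO replicate 2 or AC220 replicate 3 none of these 4 was called, with adjusted p of 0.141, 0.167 and 0.167 for PSAT1, 0.0832, 0.113 and 0.117 for DUSP6, 0.135, 0.134 and 0.149 for BCL2L11 and 0.118, 0.180 and 0.206 for PSPH, and without AC220 replicate 2 those of PSAT1, BCL2L11 and PSPH were 0.111, 0.0559 and 0.0692, while ATF4 passed without MV4-11 AC220 replicate 1 (0.0293). By limma on the deposited normalised values none of the 4 was called (adjusted p = 0.0623 for PSAT1, 0.0613 for DUSP6, 0.0649 for BCL2L11 and 0.0522 for PSPH), and without both OCI-AML3 libraries numbered 3 the calls on PSAT1 (0.136), BCL2L11 (0.0614) and PSPH (0.160) were lost. PSAT1 also lost its call with median-ratio size factors (0.0560) and after correction for GC content (log2 fold change 0.12, adjusted p = 0.268). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 489 genes (3.95%), 426 up and 63 down, of which 26 rose and 1 fell by at least 2-fold.

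Among the largest rises in OCI-AML3 were BEX2, from 0.392 ± 0.419 to 3.84 ± 1.96 CPM, and PNMA1, from 1.82 ± 0.563 to 5.63 ± 2.54 CPM. THOC3, of the THO complex of mRNA export, rose from 9.61 ± 2.87 to 27.7 ± 14.4 CPM, ST20-MTHFS from 3.14 to 8.26 CPM and GRIP2 from 2.82 to 7.32 CPM. ST20-MTHFS is a readthrough locus that overlaps its parent genes. The largest falls were those of KCTD21 (1.85 to 0.772 CPM), NBPF20 (6.54 to 3.53 CPM, a family of near-identical copies), the ATP-gated channel P2RX4 (7.81 to 4.47 CPM), the xylosyltransferase XYLT2 (17.0 to 11.6 CPM) and the histone HIST1H4C (793 ± 76.5 to 545 ± 53.4 CPM). Of these 10 genes HIST1H4C alone kept its call without each single library. In OCI-AML3, leaving out DMSO replicate 2 took the call from the other 9 (adjusted p from 0.0830 for ST20-MTHFS to 0.252 for XYLT2), DMSO replicate 1 from 8 of them, not ST20-MTHFS (0.0769 for GRIP2 to 0.196 for THOC3), AC220 replicate 3 from 8, not THOC3 (0.0573 for ST20-MTHFS to 0.179 for NBPF20), AC220 replicate 2 from BEX2, THOC3, KCTD21, NBPF20 and XYLT2 (0.0745 to 0.112), DMSO replicate 3 from KCTD21 (0.0905) and XYLT2 (0.0589), and AC220 replicate 1 from XYLT2 (0.129). Leaving out an MV4-11 library took it from THOC3 for each of the 6 (0.0511 without AC220 replicate 1 to 0.0783 without DMSO replicate 2), from XYLT2 for the DMSO replicates and AC220 replicate 2 (0.0544 to 0.0687), from BEX2 for DMSO replicates 2 and 3 (0.0629 and 0.0547) and from KCTD21 for DMSO replicate 2 (0.0509). BEX2, PNMA1, THOC3, KCTD21, NBPF20, P2RX4 and XYLT2 also lost their calls under other alternatives. Cytosolic aminoacyl-tRNA synthetases formed the 1 list of 21 that camera called, with 4 of 20 lower (4 adjusted over the list alone), SARS, WARS, AARS and CARS, by 0.22 to 0.32 on the log2 scale. That call (adjusted p = 0.0465) was lost at adjusted p = 0.853 with an estimated correlation. In serine synthesis 2 genes rose and 1 fell of 14 (4 and 1 adjusted over the list alone), in the ATF4 list 3 rose of 19 (3 rose and 3 fell adjusted over the list alone), and in MAPK output 2 rose of 16 (2 adjusted over the list alone). None of 13 amino acid transporters, 25 DNA replication genes or 15 STAT5 targets passed (0, 4 and 0 adjusted over the list alone), and 1 of 20 mitosis genes rose (3 rose and 1 fell adjusted over the list alone). Over the lists with no camera call, median, mean and test differed in sign in 10.

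The number of calls in OCI-AML3 rested on which libraries entered, from 13 without OCI-AML3 DMSO replicate 1 to 1139 without MV4-11 AC220 replicate 1, and it was 15 without OCI-AML3 DMSO replicate 2 and 22 without OCI-AML3 AC220 replicate 3. Of 478 calls with a mean count over 50, 452 had the sign of the main axis of variation among the MV4-11 replicates. The share of calls that were up, 87.1%, was 74.2% with median-ratio size factors, 72.1% by DESeq2 and 65.4% after correction for GC content.

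The third comparison tested whether the responses differed between the lines, as an interaction. Serine synthesis, the ATF4 list, amino acid transport, MAPK output and the cell cycle lists fell in MV4-11 relative to OCI-AML3, where camera called none of them. The difference of log2 fold changes was -5.11 for PHGDH (SE 0.117, adjusted p = 9.55e-24), -4.46 for PSAT1 (SE 0.0983, adjusted p = 6.69e-24), -5.40 for TRIB3 (SE 0.153, adjusted p = 1.19e-21) and -4.51 for DUSP6 (SE 0.163, adjusted p = 3.21e-19). MYC differed by -2.18 (SE 0.526, adjusted p = 0.00866) and passed in neither line alone, though without MV4-11 AC220 replicate 1 it passed in MV4-11 (-1.42, adjusted p = 0.00820) and in OCI-AML3 (1.27, adjusted p = 0.0341), and it also passed in both by DESeq2 (adjusted p = 0.0268 and 0.0223) and limma-voom (0.00189 and 0.00573), and in MV4-11 by limma on the deposited normalised values (0.00735). It stood at 43.2 ± 7.87 and 22.7 ± 11.4 CPM in MV4-11 under DMSO and AC220, and at 20.2 ± 6.15 and 48.6 ± 13.7 CPM in OCI-AML3. In replicates 1 to 3 of OCI-AML3 it had 16.2, 17.1 and 27.3 CPM under DMSO and 33.8, 51.1 and 61.0 CPM under AC220. These libraries lie in the same order along the main axis of variation among the MV4-11 replicates. The OCI-AML3 part of the MYC difference thus cannot be told apart from library variation along that axis. FLT3 (-0.23, adjusted p = 0.683) and BCL2L11 (0.11, adjusted p = 0.657) did not differ past the threshold, but FLT3 did without MV4-11 AC220 replicate 1 (-0.57, adjusted p = 0.0174). In all, 5792 genes differed, 2849 with the higher and 2943 with the lower change in MV4-11, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

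Per list, 12 of 14 serine synthesis genes, 19 of 19 ATF4 genes, 12 of 13 transporters, 18 of 20 synthetases, 11 of 16 MAPK genes, 25 of 25 replication genes and 20 of 20 mitosis genes had the lower change in MV4-11, with the same numbers adjusted over the list alone. Lysosome genes had the higher change in 13 of 20 (13 adjusted over the list alone, camera adjusted p = 0.000194). Camera called 15 of 21 lists, 13 lower and 2 higher, and 12 held with an estimated correlation. Those lost were STAT5 targets (adjusted p = 0.117 with an estimated correlation), immature myeloid genes (0.0709) and heat shock genes (0.168). Fry called 17 lists, these among them. Monocyte and granulocyte genes were not called. The largest differences lay in genes that one group hardly expressed, so their fitted sizes depend on the prior count. The calls on AKR1C2, GDAP1L1, GABRG1 and GASK1B held under every alternative that tested them. Without 1 OCI-AML3 library the adjusted p was 0.9999 for ENHO (DMSO replicate 2), OCSTAMP (AC220 replicate 1) and XIRP1 (AC220 replicate 3), and 0.9998 for F13A1 (DMSO replicate 3). In the same way it was 0.0581 for IGF1 (DMSO replicate 2) and 0.0875 for SLC4A3 (DMSO replicate 1). Each of these calls thus rests on a single OCI-AML3 library, and the test does not decide whether the responses of these genes differed. IGF1, ENHO, SLC4A3 and F13A1 rose in MV4-11 and stayed below 0.1 CPM in OCI-AML3, and GASK1B rose from no counts to 0.886 CPM in MV4-11 with 2.42 and 2.63 CPM in OCI-AML3. OCSTAMP, GDAP1L1, XIRP1 and GABRG1 fell in MV4-11 from levels that OCI-AML3 never reached, and AKR1C2 fell to no counts in MV4-11 and stood at 10.7 ± 0.198 and 12.3 ± 1.75 CPM in OCI-AML3.

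Across the 12392 genes the log2 fold changes of the lines had a Spearman correlation of -0.0772 (Pearson -0.0530), where genes are not independent replicates. Of the genes that rose in OCI-AML3, 91 rose in MV4-11, against 134 from independent lists (Fisher's exact test, two-sided p = 2.74e-06, 1.10e-05 adjusted over the 4 overlaps), and 149 fell there, against 114 (exact p = 0.000186, adjusted 0.000373). Of those that fell in OCI-AML3, 26 fell in MV4-11, against 16.9 (exact p = 0.0146, adjusted 0.0194), and 22 rose, against 19.8 (exact p = 0.587, adjusted 0.587).

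**Figure D3:**
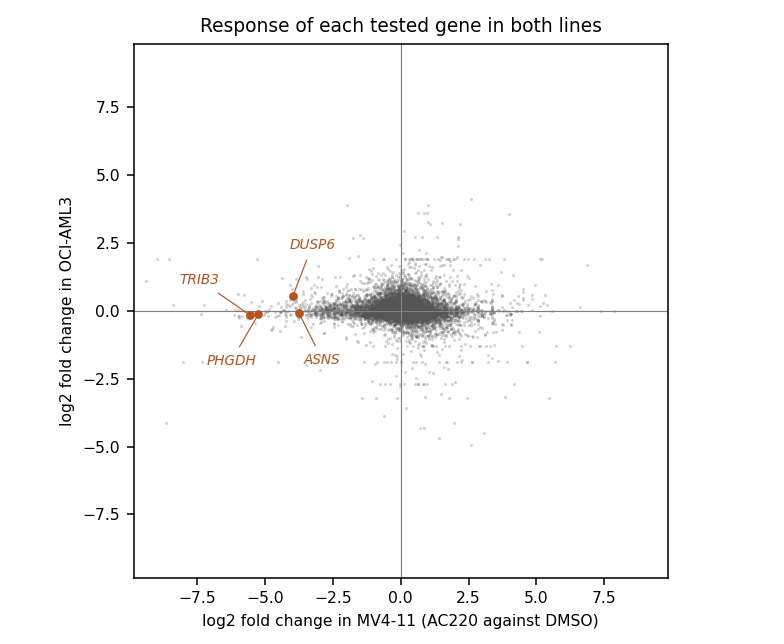
Fitted log2 fold change of each of the 12392 tested genes in OCI-AML3 (vertical) against MV4-11 (horizontal), AC220 against DMSO, with PHGDH, TRIB3, ASNS and DUSP6 marked. PHGDH lies at -5.24 in MV4-11 and -0.13 in OCI-AML3, and points aligned at one height are genes with few counts, whose fitted values depend on the prior count.

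The fourth comparison set the lines against each other under DMSO, where FLT3 and several STAT5 targets were higher in MV4-11, though camera did not call the STAT5 list. FLT3 was 18.4-fold higher in MV4-11 (218 ± 22.8 against 11.9 ± 1.63 CPM, log2 difference 4.20, SE 0.299, adjusted p = 1.64e-06). PIM1 (5.86), CISH (4.37), SOCS2 (4.45), PIM2 (2.14), CCND2 (7.04) and DUSP6 (2.98) were higher in MV4-11 on the log2 scale. In serine synthesis PSAT1 was 1.18-fold higher in MV4-11 (adjusted p = 0.00141), and SHMT2 stood at 285 against 295 CPM (adjusted p = 0.548). PHGDH was higher by 0.19 on the log2 scale (adjusted p = 0.0184), a call lost after correction for GC content (adjusted p = 0.554) and without MV4-11 DMSO replicate 1 (0.0588), MV4-11 DMSO replicate 2 (0.0538) or OCI-AML3 DMSO replicate 3 (0.167). TRIB3 was 4.70-fold higher in MV4-11, and ASNS was 1.72-fold and ATF4 1.27-fold higher in OCI-AML3. By the same test 8120 of 12392 genes differed, 3981 higher and 4139 lower in MV4-11, between 1 line of each kind.

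SNRPN and SNURF, which share an imprinted locus and largely the same reads, stood at 128 ± 4.33 and 127 ± 4.65 CPM in MV4-11 with no counts in OCI-AML3 DMSO, at least 1697-fold and 1690-fold higher. OCSTAMP, TMEM233 and HMX2 were at least 828-fold, 698-fold and 503-fold higher in MV4-11. TIMP3, an inhibitor of metalloproteinases, stood at 364 ± 8.38 CPM in OCI-AML3 and at 1 count over the MV4-11 DMSO libraries (ratio 17625, 95% counting interval 3163 to 696192). PPFIA2, NT5C3B, C12orf75 and INPP4B, a phosphoinositide phosphatase, were at least 1091-fold, 758-fold, 728-fold and 697-fold lower in MV4-11, and SPRY4 at least 56.2-fold. Of 20 interferon response genes 15 were lower and 1 higher in MV4-11 (15 and 1 adjusted over the list alone), with MX1 at 0.536 against 68.9 CPM, OAS3 at 0.480 against 94.1 CPM and OAS2 at 11.1 against 112 CPM. It was the 1 list of 21 that camera called (adjusted p = 1.48e-06), and the call was lost at adjusted p = 0.680 with an estimated correlation. Fry, which makes no comparison with other genes, called 15 lists, interferon response and STAT5 targets among them. Among 15 STAT5 targets 9 were higher and 3 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.0509). In DNA replication 3 were higher and 14 lower of 25 (3 and 14 adjusted over the list alone, camera adjusted p = 0.0917).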

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

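The tests on the number of calls in MV4-11 were chosen after the result was seen, and the splits of the libraries before. The results here were picked out because the response to AC220 differed between the cell lines in a test of the interaction.

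The number of genes that differed was 5792. Median differences of log2 fold changes (MV4-11 minus OCI-AML3) were -1.95 in serine synthesis, -3.17 in the ATF4 list, -2.26 in amino acid transporters, -1.07 in aminoacyl-tRNA synthetases, -0.68 in STAT5 targets, -2.92 in MAPK output, -0.66 in MYC and nucleolar genes and -0.73 in purine and pyrimidine synthesis. They were -0.63 in glycolysis, -0.60 in cholesterol and fatty acid synthesis, -2.54 in DNA replication, -2.54 in mitosis, 0.53 in lysosome and autophagy, 0.33 in immature myeloid genes and -0.67 in heat shock genes. The camera calls on STAT5 targets, immature myeloid genes and heat shock genes were lost with an estimated correlation (adjusted p = 0.117, 0.0709 and 0.168). With STC2, which had no counts in MV4-11 AC220, at its bound the ATF4 median was -2.87, and without SPRY4, which had no counts in MV4-11, that of MAPK output was -3.30. Among key genes the difference was -5.11 for PHGDH, -4.46 for PSAT1, -1.98 for PSPH, -1.17 for SHMT2, -2.39 for MTHFD2, -1.57 for ATF4, -3.65 for ASNS, -2.34 for DDIT3, -5.40 for TRIB3 and -4.69 for CHAC1. It was -3.27 for SLC7A11, -3.79 for SLC7A5, -2.70 for SLC3A2, -2.97 for PIM1, -0.59 for CISH, -4.51 for DUSP6, -2.18 for MYC and -1.35 for CCND2. The MYC level in OCI-AML3 followed the order of its libraries along the main axis of variation among the MV4-11 replicates. The call on CCND2, which had 18 counts in OCI-AML3 DMSO, was lost with thinned counts (-0.56, adjusted p = 0.471), without OCI-AML3 DMSO replicate 2 (0.0653) and without OCI-AML3 AC220 replicate 3 (0.194). That on CISH was lost by limma-voom (0.0930), by limma on the deposited values (0.0914), and without MV4-11 AC220 replicate 3 (0.0610) or OCI-AML3 DMSO replicates 1 (0.0684) or 2 (0.103) or OCI-AML3 AC220 replicates 1 (0.0659) or 2 (0.106). Genes that one group hardly expressed have no interpretable size, and their adjusted p by edgeR's quasi-likelihood test was 0.00101 for ENHO, 0.00110 for IGF1, 0.0145 for F13A1, 0.00323 for SLC4A3, 1.66e-05 for GASK1B, 0.00264 for OCSTAMP, 4.52e-06 for GDAP1L1, 0.0132 for XIRP1, 2.84e-10 for AKR1C2 and 0.00176 for GABRG1. Without 1 OCI-AML3 library ENHO, IGF1, F13A1, SLC4A3, OCSTAMP and XIRP1 were no longer called. The adjusted p of these genes thus rests on a single OCI-AML3 library and does not decide whether their responses differed.

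Of 100 splits of the treatment labels within each line, only 1, the real one with 5792 genes, gave as many differing genes. For that count this argues against labels that are chance in both lines at once. The highest of the others, 5505, kept the MV4-11 labels and exchanged those of OCI-AML3. The count thus rests mostly on the MV4-11 labels and hardly tests those of OCI-AML3. For AC220 in MV4-11 (7228 genes), AC220 in OCI-AML3 (489) and the lines under DMSO (8120), the 10 splits of 6 libraries are too few for a share under 0.05, and in each 1 split, the real one, gave as many genes and the highest of the others gave 0. Those other splits mix libraries of both groups, so a difference between the groups adds to the spread within each part. The 0 calls therefore tell nothing about the spread among replicates.

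Depth and GC content were weighed for the number of genes changed in MV4-11, since its AC220 libraries had the lower totals. With all libraries thinned to the smallest total 7008 genes were called, and after removal of each library's GC trend 7432, of which 6791 were among the 7228. Both values argue against these as the whole cause. Spread among replicates as the cause of that count is argued against by the second principal component. On it the MV4-11 DMSO libraries lay from -54.0 to -51.9 and the MV4-11 AC220 libraries from 40.3 to 47.4. The splits other than the real one called 0 genes, but they mix DMSO and AC220 libraries and so do not bear on this spread. The 10 splits alone are also too few to exclude chance labels. A response to AC220, the treatment the design names, cannot be told apart from another difference between these groups, since separate cultures are not stated.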

How the results depend on the processing

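Thinning, GC correction, the library score and leaving out both OCI-AML3 libraries numbered 3 were chosen after seeing the data. The counts of changed genes in MV4-11 (5930 to 7548), of genes that differed between responses (4376 to 6110) and of genes that differed under DMSO (6946 to 8471) stayed within 1.5 times of their main values under every alternative except a minimum absolute log2 fold change of 1, which left 2289, 2287 and 3374 by its own construction. The list counts of MV4-11 (12 to 17) and of the difference (12 to 17) stayed within 1.5 times. The number of genes changed by AC220 in OCI-AML3, 489, did not: it was 836 with no filter on low counts, 813 by DESeq2, 118 by limma on the deposited normalised values, 27 at an absolute log2 fold change of 1, 47 at an adjusted p under 0.01, 245 without both OCI-AML3 libraries numbered 3 (fewer samples) and 2 with the library score as covariate. That score had a correlation of 0.857 with treatment, and 78 of 100 random covariates with the same correlation left under 50% of the calls, so this fit decides nothing. Leaving out 1 library gave 13 (without OCI-AML3 DMSO replicate 1) to 1139 (without MV4-11 AC220 replicate 1), with 15 without OCI-AML3 DMSO replicate 2, 22 and 116 without OCI-AML3 AC220 replicates 3 and 2, and 999 and 947 without OCI-AML3 DMSO replicate 3 and OCI-AML3 AC220 replicate 1. The fit that treats the replicate number as a block called 764 genes there, of which 484 were among the 489. It moved no other count by over 1.5 times, and FLT3 in MV4-11 was not called in it (adjusted p = 0.0902). The numbers did not pair the libraries in MV4-11, where the correlation of deviations between libraries of one number ran from -0.223 to -0.111. In OCI-AML3 it ran from 0.0589 to 0.293, so pairing by number is left open there. Over both lines 2 of 6 correlated best with their own number, OCI-AML3 replicates 1 and 3. The 1 list called in OCI-AML3 became 0 with an estimated correlation and 0 by fry, and 0 to 3 leaving out 1 library. Of 39 called values of named genes in MV4-11, that of FLT3 lost its call in some alternative, and all 14 in OCI-AML3 did (HIST1H4C only with the library score), 8 of 28 in the difference and 4 of 29 under DMSO. With the library score THOC3 (-0.17) and GRIP2 (-0.025) in OCI-AML3 turned direction. Sign changes of values past the threshold under neither setting were not counted. The cause of these shifts was not tested, except where stated. The correlation of responses stayed below 0 (-0.0853 and -0.0530). GC correction moved the median of all genes in MV4-11 to 0.11 from 0.07 and the difference to 0.11 from 0.03. Depth limits genes near 0.177 to 0.276 CPM, the level of 3 counts.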

Other observations

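Of the tests here, that on the GC content of MV4-11 AC220 replicate 1 was set before its result was seen, with its interval added afterwards, and the others were chosen after their results were seen. The gene groups of the next paragraph were also chosen after seeing the data. Their camera p-values come from those same data and were adjusted over these groups alone, so they are not independent evidence.

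In MV4-11, antigen presentation genes of MHC class II were higher after AC220, 10 of 10 measured members by edgeR's quasi-likelihood test (10 adjusted over the list alone). HLA-DRA rose from 29.9 to 385 CPM, HLA-DRB1 from 35.3 to 230 CPM and CD74, the invariant chain, from 137 to 730 CPM, while CIITA, the coactivator of this group, rose from 43.9 to 53.9 CPM. The median log2 fold change was 3.51 (camera adjusted p = 9.45e-08, and adjusted p = 0.0528 with an estimated correlation). HLA genes have close paralogs and many alleles, so their reads could be divided or lost. MHC class II is also expressed by B cells, and among their markers CD79A rose from 0.521 to 4.06 CPM and PAX5 from 0.887 to 3.89 CPM. MHC class I genes moved less, with 6 of 9 up and 1 down (6 and 1 adjusted over the list alone), B2M from 774 to 1193 CPM among them, and TAP2, a peptide transporter subunit, fell from 35.8 to 18.8 CPM (camera adjusted p = 0.0467, and adjusted p = 0.129 with an estimated correlation). All 6 measured inflammatory cytokines and chemokines fell (6 adjusted over the list alone), TNF from 53.9 to 1.95 CPM and IL1B from 6.10 to 0.0923 CPM (camera adjusted p = 0.00120, and adjusted p = 0.0879 with an estimated correlation). OSM of this group is also a listed STAT5 target. Of 10 genes of transsulfuration and glutathione 5 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.0467, and adjusted p = 0.0952 with an estimated correlation). CBS and CTH, the latter also in the ATF4 list, the enzymes that make cysteine from homocysteine and serine, fell from 75.9 to 1.07 CPM and from 25.8 to 1.49 CPM, and GPX1, a glutathione peroxidase, rose from 313 to 501 CPM. In OCI-AML3 CBS stood at 341 and 305 CPM under DMSO and AC220, and TNF at 22.6 and 25.6 CPM, and the responses differed between the lines (interaction -5.99 and -4.94, adjusted p = 3.63e-16 and 1.31e-17). Of the MHC class II genes CD74, CIITA and HLA-DMA differed in response, and most others had few or no counts in OCI-AML3.

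The calls under AC220 in OCI-AML3 lie along an axis of library variation that is also present among MV4-11 replicates. That axis, the first component of deviations within the MV4-11 groups, held 43.8% of their variance and was set mainly by MV4-11 AC220 replicate 1. Of the 478 OCI-AML3 calls with a mean count over 50, 94.6% had its sign. Of all genes with such a count 46.9% were positive on it, which is not a rate of agreement in sign. Over these genes the OCI-AML3 log2 fold changes had a Spearman correlation of 0.534 with the axis, so the agreement is not particular to the calls. GC content as the whole cause is argued against by the 610 genes called after removal of GC trends, 353 of them among the 489, though GC content had a Spearman correlation of -0.444 with the axis and of -0.363 with the log2 fold changes in OCI-AML3 (0.0907 in MV4-11), so it may hold part of the pattern. Argued against is also a smaller form of the MV4-11 response as the whole cause, by the 91 genes that rose in both lines, below the 134 of independent lists, though 26 fell in both, above 16.9 (Fisher's exact test, adjusted p = 0.0194). These counts do not decide whether it was a part of the cause. The axis had a Pearson correlation of -0.121 with the MV4-11 log2 fold changes, so calls along it would share fewer rises, and the exact test treats genes as independent. Library variation along that axis and a response of OCI-AML3 to AC220 cannot be told apart, since the score of the libraries on it and the treatment had a correlation of 0.857, and 78 of 100 random covariates with that correlation left under 50% of the calls.

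MV4-11 AC220 replicate 1 differed from the other libraries of its group in 124 genes by at least 2-fold, 98 of them higher. Untreated cells in that library are argued against: over 15 transcripts that fell at least 16-fold the median share of the DMSO level was 0.00349% (95% bootstrap interval -0.106 to 0.682), where the 39 differing genes that lay between the levels of both groups needed 16.2% at their lower quartile. The 15 transcripts were picked in a fit that included this library, which caps the share they could show, but untreated cells would raise each of them. GC content may be the cause or not, which cannot be told apart here, since after removal of GC trends the library stayed 6.75% (3.56 to 10.5) farther from its nearer neighbour than the others from each other, and the bound set beforehand was 5%. No biological explanation was tested, as the labels give none for a single library.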
